A study of Mus musculus with 23 samples.

How the data were processed

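Total RNA from mouse lungs was measured on Affymetrix arrays, 1 array per sample. The 23 arrays were grouped from the sample titles into 11 groups: 3 naive mice, 15 mice vaccinated by the pulmonary route (3 at each of 5 times after challenge) and 5 pools of subcutaneously vaccinated mice, 1 at each time. The number of mice in a pool, the hour of the day at which lungs were taken and a processing batch are not given in the sources used here.

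The deposited values were on the log2 scale and, per the labels, had been background-corrected, quantile-normalized and summarised by the authors with RMA, whose version is not given in the sources used here. They held 17856 probe sets, 1 per gene, with 0 missing values. Their names carry Entrez Gene numbers, which gave a gene symbol for 17216 probe sets, and 0 of these symbols differed from the RefSeq annotation. The other 640 probe sets were tested but are not named. Genome coordinates play no part in array values of this kind and are left out. Array medians lay between 5.06 and 5.17 on the log2 scale, and the median of a group differed from that of the naive group by at most 0.06. Arrays have no read depth, so their number limits the precision.

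Values were analysed as deposited, with no filter, in R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group was fitted over all 23 arrays, and variances were moderated across genes (12 residual degrees of freedom, all from the 6 groups of 3 mice). Each pulmonary group and each subcutaneous pool was compared with the naive mice, and each pulmonary group with the pool of its time. In this fit a pool adds nothing to the estimate of the spread. In each of its comparisons with a pool, the pool is therefore assumed to vary like a single mouse, with no replicate check. The route of vaccination was also tested over the 20 arrays of challenged animals with time as a further term (14 residual degrees of freedom). There the pools, and changes of the route difference with time, enter the spread. A moderated F test covered any difference over the naive and 5 pulmonary groups, and another the change of the route difference with time. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 17856 genes of a comparison, with 0.05 as the threshold.

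Sets of genes were tested with camera at a preset correlation between genes of 0.01, for 39 lists of cell type markers, tissue markers and pathways in each of 16 comparisons. These p-values were adjusted over the lists and the comparisons of one kind. Camera was repeated with the correlation estimated from the data, and the limma test fry was run beside it. Members of a list were counted at an adjusted p over all genes and again adjusted over the list alone.

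Genes were named by a rule. For each pulmonary group against naive, the 5 largest rises and 3 largest falls were taken among genes past the threshold whose 3 mice all lay beyond all 3 naive mice. For each pool against naive and each pulmonary group against its pool, the 3 largest rises and 3 largest falls past the threshold were taken. For the route over all times, the 10 highest and 10 lowest were to be taken, or, with fewer than 3 past the threshold, the 5 smallest p-values in each direction. For each list described, up to 4 members with the largest absolute difference were taken, with further members where a count of 5 or fewer is named. Any gene named beyond this rule is said to have been singled out after its values were seen. The groups, comparisons, 39 lists, rule for named genes and alternatives were fixed before the data were examined, except where a test or alternative is said to have been chosen later.

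The fits were tested on simulated data with the spread of the real arrays. Of genes changed 1.5-fold, 89.6% were recovered for 3 mice against 3 naive mice, 64.2% for 1 pool against 3 naive mice and 92.5% for the route over all times, with 7, 6 and 9 false calls. At 2-fold the shares were 94.0%, 92.5% and 100%. In each simulation 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold at once, with independent noise. A pool was given the spread of a single mouse. Recovery at an adjusted p depends on how many genes change. The real pools had 1, 108, 1, 22 and 6 genes past the threshold, so the shares for a pool may be too high for them. The simulated route difference was the same at all times, with the spread of mice within groups. In the real route fit, differences that change with time add to the spread, so the shares for the route are too high for it.

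Alternatives were a trend and robust prior for the variances, the removal of probe sets under the 30th percentile of mean value, a further quantile normalization, centring of each array on its median, a minimum of 1.5-fold, array weights, a fit of 2 groups alone and the omission of each mouse or time in turn. For the route, a test on 5 pairs and the mean of the 5 single contrasts were added. Counts of other splits of the arrays and tests on 3 further marker lists are given with the closing observations. All splits were counted for each pulmonary group against naive mice. Random draws were used for the F test over groups and for the route over all times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.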

Results

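Gene expression was measured in lungs of female BALB/c mice in a study of the route by which a vaccine against whooping cough is given. The labels give an age of 8 weeks for all mice, without the point of the schedule to which it applies. The vaccine, made of outer membrane vesicles of Bordetella pertussis, was given at 1 µg of protein on days 0 and 28, either into the lungs (pulmonary) or under the skin (subcutaneous). Mice were then challenged with 200000 colony-forming units of the bacterium. Lungs were taken at 4 h, 2 d, 7 d, 14 d and 28 d after challenge. The 23 arrays comprise 3 naive control mice at day 0, 15 pulmonary mice (3 per time) and 5 subcutaneous pools (1 per time). Each array gave log2 values for 17856 genes, with array medians from 5.06 to 5.17, and the number of arrays limits the precision. Vaccinated mice without challenge and challenged mice without vaccine are not analysed here, so a difference from naive lungs combines both. Age and day of collection may also differ from those of the naive mice, and cannot be told apart from these. Values for pools have no replicates. No call of signal over background was used, and the lower quartile of an array was 3.86 to 3.93 log2. Where the lower of a pair of levels lies under it, a fold is approximate and has no rank among other folds. Among named genes this holds at least for the naive levels of Cxcl2, Il6, Cxcl3, Cxcl5, Ighg1, Gm19325, Gemin8, Serpinb2, Timd4, Il17a and Ifng. It also holds for Il6 in the subcutaneous 4 h pool and for Il12a in the 14 d pool.

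Over the naive mice and the 5 pulmonary groups, 6823 of 17856 genes differed (moderated F test in limma, adjusted p under 0.05). Pulmonary mice differed from naive mice in 5163 genes at 4 h, 1447 at 2 d, 877 at 7 d, 34 at 14 d and 75 at 28 d. Pearson correlations across genes with the naive arrays were 0.964 to 0.980 for the 4 h arrays and 0.978 to 0.992 for the 2 d arrays, against 0.996 to 0.997 among the naive arrays. Genes are not independent replicates in these correlations.

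**Figure D1:**
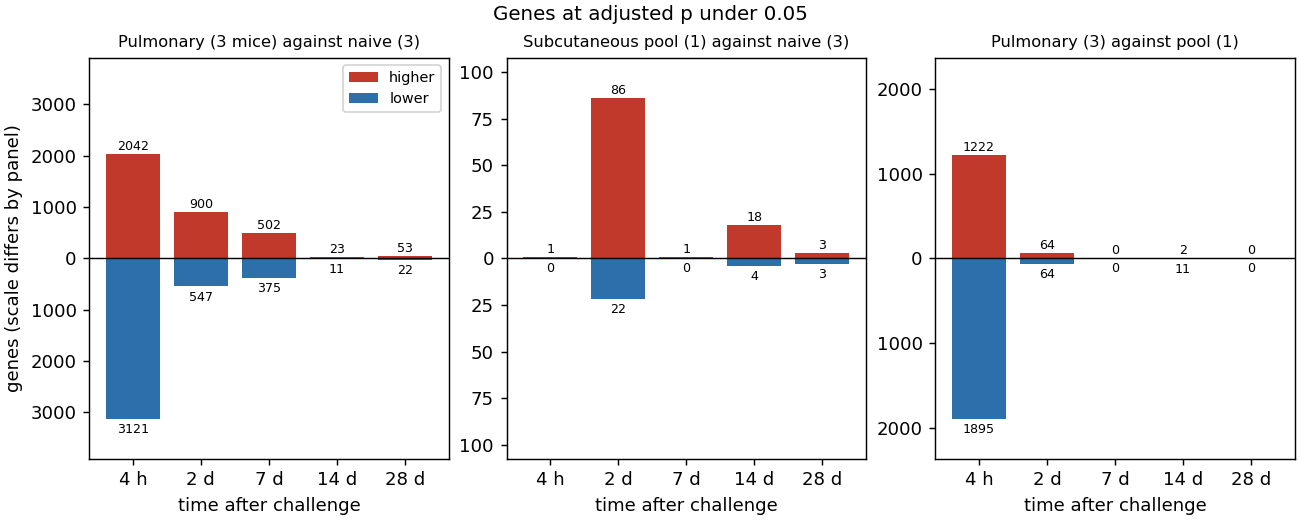
Number of genes higher (bars above 0) and lower (bars below 0) at an adjusted p under 0.05, by time after challenge, for pulmonary mice against naive mice, subcutaneous pools against naive mice and pulmonary mice against the pool of the same time. The vertical scale differs between panels, and the tallest bars are the 2042 genes higher and 3121 genes lower in pulmonary mice at 4 h.

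The first comparison asks how the vaccinated lung differs from the naive lung soon after challenge. At 4 h, chemokines that attract neutrophils and cytokines of acute inflammation rose in pulmonary mice. Cxcl2 was about 179-fold higher (11.22 ± 0.83 against 3.74 ± 0.10 log2, SD, n = 3 each), a log2 difference of 7.49 with a standard error of 0.55 (adjusted p = 8.5e-08). Cxcl1 was 120-fold higher, Il6, an inducer of the acute phase response, about 110-fold, Ccl20, which attracts dendritic cells and lymphocytes, 71.3-fold, and Cxcl3 about 62.6-fold. The largest falls were in Meox2 and Meis1, which encode homeobox transcription factors, with log2 differences of -2.36 and -2.16 (standard errors 0.16 and 0.13). Bank1, which encodes an adaptor of B cell receptor signalling, followed at -1.95 (standard error 0.20). In total 2042 genes rose and 3121 fell. Here and at the later times, each gene named first lay beyond all 3 naive mice in all 3 pulmonary mice.

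All 26 measured inflammatory cytokines and chemokines rose at 4 h (26 adjusted over the list alone; camera adjusted p = 6.9e-25, but adjusted p = 0.16 with an estimated correlation). All 13 genes of the glucocorticoid response rose (13 adjusted over the list alone), among them the metallothioneins Mt2 and Mt1, with log2 differences of 5.44 and 3.75, Pdk4, a regulator of fuel use, at 3.66, and Zbtb16 at 3.59. Of 16 immediate early genes 14 rose (15 adjusted over the list alone), led by Atf3 at 4.92, Junb at 3.28 and Egr1 at 3.12. These last 2 calls hold with an estimated correlation (adjusted p = 0.0082 and 0.047), and they are the only 2 of the 15 lists called at 4 h that do. Dusp1 is a member of both lists. Of the glucocorticoid list, Lcn2 is also in the acute phase and Th17 lists and Per1 in the clock list. Of 19 neutrophil genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), including Il1r2 at 3.81, Clec4e at 3.63, Clec4d at 3.23 and the chemokine receptor Cxcr2 at 3.07. That list had a camera adjusted p = 3.7e-07 and an adjusted p = 0.21 with an estimated correlation. Pulmonary mouse 8 stood apart, with a mean of the neutrophil list of 6.54 log2 against 7.53 and 7.37 in the other mice, and of the inflammatory list of 8.17 against 9.87 and 9.32 (naive 5.21 to 5.36). Of 18 genes of the Th17 list 13 rose (13 adjusted over the list alone), with Cxcl1 at 6.90, Ccl20 at 6.16 and Cxcl5 at 5.33, and Ccr6, Ahr and Il17rc fell at -0.85, -0.54 and -0.33. The camera adjusted p was 2.9e-07, and adjusted p = 0.15 with an estimated correlation. Cxcl1, Ccl20 and Cxcl5 are also members of the inflammatory list, so the call in part repeats that one. Of 21 B cell genes 12 fell and 1 rose (13 and 1 adjusted over the list alone). Bank1, Ms4a1 at -1.84 and Fcmr at -1.29 were among those that fell, and Bcl6, a transcriptional repressor, rose with a log2 difference of 1.21 (camera adjusted p = 4e-04, adjusted p = 0.55 with an estimated correlation). Red blood cell markers moved alongside: all 4, Alas2, Bpgm, Slc4a1 and Car2, fell, at -1.03, -1.01, -0.67 and -0.48 (4 adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.26 with an estimated correlation). With a minimum of 1.5-fold the count of genes was 1639, and without pulmonary mouse 8 the log2 difference of Cxcl3 was 6.62 in place of 5.97.

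At 2 d the acute phase gene Saa3 was 61.3-fold higher in pulmonary mice (11.12 ± 1.28 against 5.18 ± 0.42 log2, SD, n = 3 each; standard error of the difference 0.59, adjusted p = 3.4e-05). The neutrophil chemokines Cxcl3 and Cxcl5, with naive levels under the lower quartile of the arrays, were about 22.6-fold and 14.7-fold higher, Wfdc17, which encodes a whey acidic protein domain, 11.1-fold, and Retnla, a macrophage gene of type 2 responses, 10.8-fold. Dbp and Nr1d1, both part of the circadian clock, had log2 differences of -2.69 and -1.82 (standard errors 0.46 and 0.18), and Pon1, which encodes paraoxonase, -2.30 (standard error 0.21). Without pulmonary mouse 12 the log2 difference of Saa3 was 5.22 in place of 5.94, and without pulmonary mouse 11 the fold of Cxcl3 was 34.2 in place of 22.6. In total 900 genes rose and 547 fell.

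Genes of dividing cells rose at 2 d, with 23 of 26 cell cycle genes higher and 0 lower (25 adjusted over the list alone). Birc5, Top2a and Cdk1, which act in mitosis, had log2 differences of 2.40, 2.28 and 2.25, and Rrm2, which makes precursors for DNA synthesis, 2.15. The camera adjusted p was 3.7e-25, and adjusted p = 0.16 with an estimated correlation. Monocyte and interstitial macrophage genes rose in 15 of 17 members (16 adjusted over the list alone), including Ms4a7 at 2.05, Ms4a6c at 2.02, Cd14 at 1.87 and C1qc at 1.83 (camera adjusted p = 3.7e-18, adjusted p = 0.16 with an estimated correlation). Complement genes rose in 10 of 13 members (12 adjusted over the list alone), with Cfb, a factor of the alternative pathway, at 2.99 (camera adjusted p = 4.4e-13, adjusted p = 0.091 with an estimated correlation). Of 23 genes of Th1 cells and interferon gamma 12 rose (15 adjusted over the list alone), with Cxcl10 at 2.72 (camera adjusted p = 2e-11, adjusted p = 0.26 with an estimated correlation). Of 18 genes induced by type I interferon 9 rose (15 adjusted over the list alone), among them Irf7 at 1.39 (camera adjusted p = 3.7e-10, adjusted p = 0.33 with an estimated correlation). Pulmonary mouse 12 stood apart, with a mean of this list of 8.17 log2 against 6.59 and 7.05 in the other mice and 6.27 to 6.34 in naive mice. The same mouse was highest in the cell cycle list, at 6.72 against 5.91 and 5.89 (naive 4.74 to 5.17), and in the monocyte and interstitial macrophage list, at 7.96 against 7.02 and 7.22 (naive 5.90 to 6.09). Of 13 genes of mucosal antibody transport and lymphoid chemokines 3 rose (3 adjusted over the list alone): Cxcl13, which attracts B cells, at 3.22, Pigr, which carries IgA across epithelium, at 1.85, and Tnfsf13b, a B cell survival factor, at 0.56 (camera adjusted p = 0.028, adjusted p = 0.38 with an estimated correlation). None of the 19 lists called at 2 d holds with an estimated correlation. The count of 1447 genes fell to 874, 639 and 693 without naive mouse 2, 3 or 4 and to 519 without pulmonary mouse 12, and was 497 with a minimum of 1.5-fold and 635 in a fit of the 2 groups alone. The share of these genes that were higher was 62.2% as deposited, 48% after a further quantile normalization and 35.6% with arrays centred on their medians.

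At 7 d, Saa3 was still the gene with the largest rise, 18-fold (9.36 ± 1.32 against 5.18 ± 0.42 log2, SD, n = 3 each; standard error 0.59, adjusted p = 0.0021). Ms4a7, a macrophage gene, was 9.05-fold higher, Vnn1, a pantetheinase, 9.02-fold, Slc26a4, an anion transporter of airway epithelium, 8.58-fold, and the monocyte chemokine Ccl8 6.86-fold. Dbp and Nr1d1 had log2 differences of -2.59 and -1.69 (standard errors 0.46 and 0.18), and Cyp1a1, a target of the aryl hydrocarbon receptor, -1.50 (standard error 0.28). Without pulmonary mouse 13 the log2 differences of Saa3, Vnn1 and Slc26a4 were 4.93, 4.07 and 3.88 in place of 4.17, 3.17 and 3.10. In total 502 genes rose and 375 fell.

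At 7 d monocyte and interstitial macrophage genes rose in 14 of 17 members (15 adjusted over the list alone), with Ms4a7 at a log2 difference of 3.18, Trem2 at 2.01, Gpnmb at 1.69 and C1qb at 1.63 (camera adjusted p = 7e-20, adjusted p = 0.15 with an estimated correlation). Genes of presentation by major histocompatibility complex (MHC) class II rose in 11 of 13 members (11 adjusted over the list alone), with Ctss at 1.13, H2-Ab1 at 0.95, H2-Ea at 0.94 and H2-DMb1 at 0.93 (camera adjusted p = 2.7e-13, adjusted p = 0.16 with an estimated correlation). Of 23 T cell genes 3 rose (5 adjusted over the list alone): Cxcr6, a receptor of lung-resident T cells, at 1.70, Thy1 at 0.78 and the costimulatory receptor Icos at 0.71 (camera adjusted p = 0.0036, adjusted p = 0.55 with an estimated correlation). Of 18 immunoglobulin genes Igha, the constant region of IgA, rose at 1.55 (1 adjusted over the list alone; camera adjusted p = 0.030, adjusted p = 0.64 with an estimated correlation). Of 16 endothelial genes Eng, Plvap, Tek and Car4 fell (10 adjusted over the list alone), with Eng at -0.58 (camera adjusted p = 9.5e-08, adjusted p = 0.26 with an estimated correlation). Of 10 smooth muscle genes Actg2, Cnn1, Tagln and Des fell (7 adjusted over the list alone), with Actg2 at -0.93 (camera adjusted p = 9.1e-06, adjusted p = 0.26 with an estimated correlation). Markers of heart and skeletal muscle, a tissue that can adhere to a lung sample, moved alongside: 0 of 17 passed over all genes and 6 were lower adjusted over the list alone, with a median log2 difference of -0.40 (camera adjusted p = 0.0025, adjusted p = 0.45 with an estimated correlation). Pulmonary mouse 13 lay nearer to naive mice than mice 15 and 16 in the monocyte list (6.74 against 7.77 and 7.52 log2), the MHC class II list (8.85 against 9.35 and 9.28), the endothelial list (9.64 against 9.30 and 9.33) and the smooth muscle list (7.08 against 6.72 and 6.73). It lay within the naive range in the immunoglobulin list, at 5.32 against 5.81 and 6.08 (naive 5.25 to 5.68), and in the T cell list, at 4.86 against 5.11 and 5.14 (naive 4.69 to 4.91). None of the 24 lists called at 7 d holds with an estimated correlation. The count of 877 genes was 529, 303 and 432 without naive mouse 2, 3 or 4, 1418 without pulmonary mouse 13, 247 without pulmonary mouse 15 and 225 without pulmonary mouse 16. The calls of Ccl8 and Cyp1a1 reached adjusted p = 0.052 and 0.051 without pulmonary mouse 15. The count was 340 with a minimum of 1.5-fold, 561 in a fit of the 2 groups alone and 1969 with array weights.

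At 14 d, 23 genes were higher and 11 lower in pulmonary mice. Ccl8 was 8.93-fold higher (8.43 ± 0.63 against 5.28 ± 0.20 log2, SD, n = 3 each; standard error 0.53, adjusted p = 0.021), the clock gene Arntl 3.71-fold, the small nucleolar RNA gene Snord14e 3.16-fold, Mgl2, a lectin of macrophages and dendritic cells, 3.08-fold, and Adm, a vasodilator peptide, 2.96-fold. Dbp, Nr1d1 and Tef, all outputs of the clock, had log2 differences of -2.82, -1.71 and -0.96 (standard errors 0.46, 0.18 and 0.14). Of 16 circadian clock genes Arntl rose and Dbp, Nr1d1, Tef, Hlf and Per3 fell (5 and 8 adjusted over the list alone; camera adjusted p = 7.9e-05, adjusted p = 0.14 with an estimated correlation). Of 18 genes of ciliated cells Cfap126 rose, with a log2 difference of 0.48 (10 adjusted over the list alone; camera adjusted p = 1.2e-12, adjusted p = 0.091 with an estimated correlation). None of the 14 lists called at 14 d holds with an estimated correlation. The count of 34 genes was 17 and 9 without naive mouse 2 or 3, and 12 and 15 without pulmonary mouse 17 or 19. The calls of Arntl, Mgl2 and Nr1d1 held with any 1 mouse left out, whereas that of Ccl8 reached adjusted p = 0.16 without pulmonary mouse 17, that of Adm 0.16 without the same mouse, that of Dbp 0.086 without naive mouse 3, that of Tef 0.064 without naive mouse 3, and that of Snord14e 0.26 without pulmonary mouse 17 and 0.061 after a further quantile normalization.

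At 28 d, 53 genes were higher and 22 lower. Ccl8 was 6.63-fold higher (8.01 ± 0.93 against 5.28 ± 0.20 log2, SD, n = 3 each; standard error 0.53, adjusted p = 0.040), and Ighg1, the constant region of IgG1, 4.72-fold (6.09 ± 1.40 against 3.85 ± 0.06). Arntl was 3.62-fold higher, AU040972 2.23-fold and Ptgs2, a prostaglandin synthase, 2.00-fold. Dbp, Cyp1a1 and Nr1d1 had log2 differences of -2.67, -2.11 and -1.57 (standard errors 0.46, 0.28 and 0.18). Ciliated cell genes were the only list of the 17 called at 28 d to hold with an estimated correlation (adjusted p = 0.047; camera adjusted p = 1.1e-16). Of its 18 members 1110017D15Rik, Cdhr3, Foxj1, the master regulator of motile cilia, Cfap126 and Dynlrb2 rose (12 adjusted over the list alone), with log2 differences of 0.63, 0.59, 0.59, 0.53 and 0.45. Of 18 immunoglobulin genes Ighg1 passed over all genes and 9 were higher adjusted over the list alone (camera adjusted p = 5.7e-09, adjusted p = 0.16 with an estimated correlation). Of 13 MHC class II genes 0 passed over all genes and 8 were higher adjusted over the list alone, with H2-Ab1 at 0.64 (camera adjusted p = 2.3e-08, adjusted p = 0.26 with an estimated correlation). The count of 75 genes was 23, 11 and 25 without naive mouse 2, 3 or 4, 48, 20 and 15 without pulmonary mouse 21, 22 or 24, 46 with a minimum of 1.5-fold, 134 in a fit of the 2 groups alone and 188 with array weights. The calls of Arntl, Cyp1a1 and Nr1d1 held with any 1 mouse left out, whereas those of Ccl8, Ighg1, AU040972, Ptgs2 and Dbp reached adjusted p = 0.18, 0.18, 0.13, 0.15 and 0.11 (without pulmonary mouse 24, naive mouse 3, naive mouse 3, pulmonary mouse 22 and pulmonary mouse 24). The log2 difference of Ighg1, 2.24 with all mice, was 1.47 without pulmonary mouse 24 (adjusted p = 0.051) and 2.84 without pulmonary mouse 21.

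**Figure D2:**
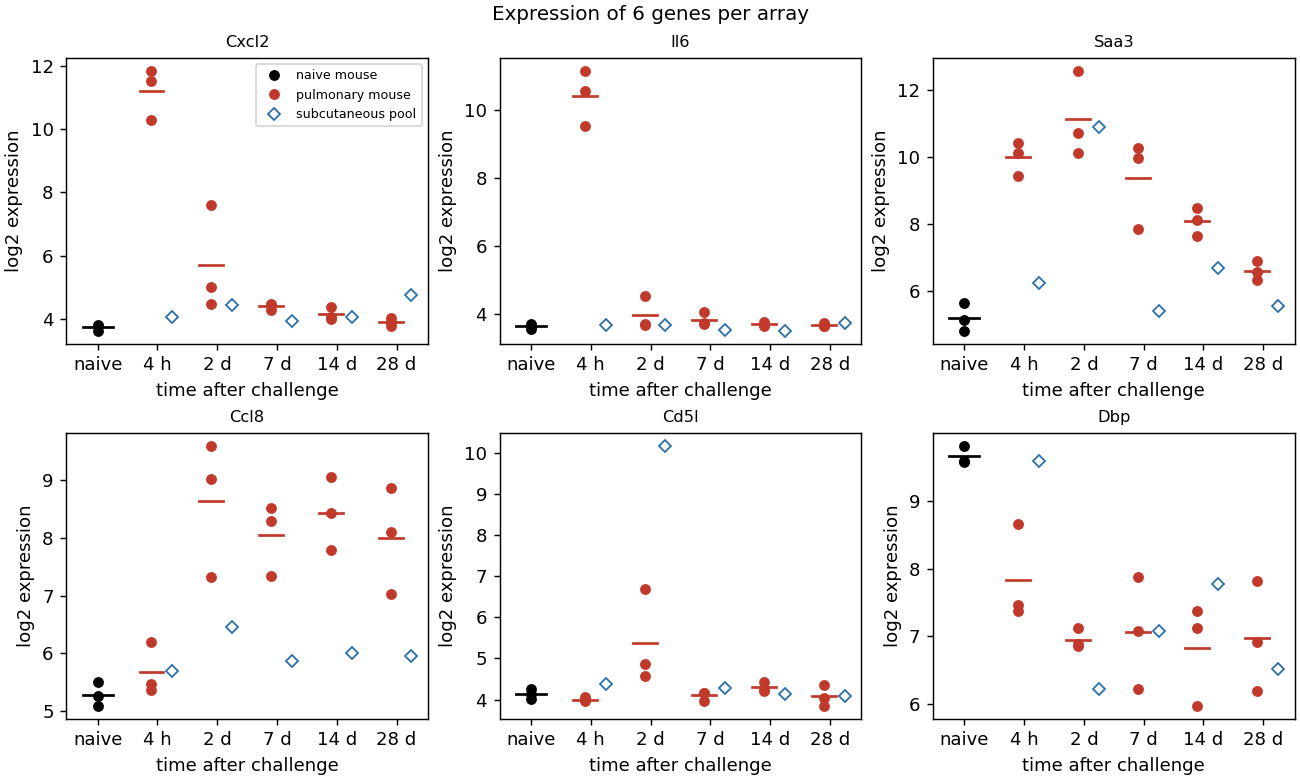
Log2 expression of Cxcl2, Il6, Saa3, Ccl8, Cd5l and Dbp (vertical axes) in naive mice and by time after challenge, with 1 filled point per mouse, lines at group means of 3 mice, and 1 open diamond per subcutaneous pool. Cxcl2 and Il6 are high in the 3 pulmonary mice at 4 h, with means of 11.22 and 10.41, and Cd5l stands at 10.17 in the subcutaneous pool at 2 d.

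Each subcutaneous pool was compared with the naive mice to see the response after vaccination under the skin. The lung pool at 4 h had 1 gene past the threshold, Gm19325, at 6.94 log2 against 3.82 ± 0.13 in naive mice (SD, n = 3), which is 8.68-fold higher (standard error of the log2 difference 0.12, adjusted p = 3.6e-10). Its spread comes from mice at low levels, such as 4.24 and 3.95 log2 in pulmonary mice at 4 h and 14 d. The p-value therefore does not measure the spread of pools at a level like 6.94. The same holds for Gm19325 in the 14 d pool and between the routes. Neutrophil genes had 0 of 19 members past the threshold over all genes and 4 higher adjusted over the list alone. Cxcr2, Mmp8, S100a8 and S100a9 lay 2.44, 2.35, 2.17 and 1.83 above naive on the log2 scale (camera adjusted p = 2.5e-07, adjusted p = 0.35 with an estimated correlation). Adipose tissue genes had a median of 0.92 and 1 of 9 higher adjusted over the list alone (camera adjusted p = 4.2e-06, adjusted p = 0.45 with an estimated correlation). The count was 2 without naive mouse 4, 3 after a further quantile normalization and 10 with array weights.

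The 2 d pool had 86 genes higher and 22 lower than naive mice. Cd5l, which encodes a protein secreted by macrophages, was 65.6-fold higher (10.17 against 4.13 ± 0.12 log2, SD, n = 3; standard error 0.50, adjusted p = 6.4e-06), Prg4, the lubricant proteoglycan lubricin, 60.1-fold and Saa3 51.8-fold. The clock genes Dbp, Per2 and Nr1d1 had log2 differences of -3.42, -1.67 and -1.58 (standard errors 0.65, 0.28 and 0.26). Of 21 B cell genes Bank1, Cxcr5 and Blk rose at 1.67, 1.30 and 1.28 (12 adjusted over the list alone; camera adjusted p = 6.8e-15, adjusted p = 0.35 with an estimated correlation). Markers of blood moved alongside. Of 4 red blood cell genes Slc4a1 rose at 1.32 (3 adjusted over the list alone; median 1.06, camera adjusted p = 2.2e-06, adjusted p = 0.22 with an estimated correlation), and of 8 platelet genes Pf4 rose at 1.89 (1 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.55 with an estimated correlation). Of 17 monocyte and interstitial macrophage genes Itgam, Adgre1 and C1qc rose at 3.67, 2.27 and 1.53 (6 adjusted over the list alone; camera adjusted p = 4.1e-08, adjusted p = 0.55 with an estimated correlation). Adipose tissue genes had 0 of 9 members past the threshold over all genes and 4 higher adjusted over the list alone, with a median log2 difference of 1.22 (camera adjusted p = 3.2e-07, adjusted p = 0.36 with an estimated correlation). Heart and skeletal muscle markers had a median of 0.43 (camera adjusted p = 0.013, adjusted p = 0.76 with an estimated correlation). The share of genes that were higher was 79.6% as deposited, 73.8% after a further quantile normalization and 60.4% with arrays centred on their medians. The count of 108 genes was 62 and 65 without naive mouse 2 or 3 and 223 with array weights. The call of Dbp reached adjusted p = 0.058 without naive mouse 2 and 0.054 without naive mouse 3.

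The 7 d pool had 1 gene past the threshold, Arntl, 4.15-fold higher (6.72 against 4.67 ± 0.11 log2, SD, n = 3; standard error 0.24, adjusted p = 0.0060). The count was 2 with array weights. In the 14 d pool 18 genes were higher and 4 lower. Gm19325 was 9.33-fold higher (standard error 0.12 log2), Cidea, a lipid droplet protein of fat cells, 4.85-fold (standard error 0.25) and Zbtb16, a transcription factor induced by glucocorticoids, 4.71-fold (standard error 0.34), with adjusted p = 2.2e-10, 0.00068 and 0.015. Il12a, Rgs2 and Tnfsf10 had log2 differences of -0.86, -0.84 and -0.67 (standard errors 0.14, 0.15 and 0.11). Of 13 genes of the glucocorticoid response Zbtb16, Pdk4, Cdkn1a and Errfi1 rose (7 adjusted over the list alone; camera adjusted p = 5.8e-16). That call holds with an estimated correlation (adjusted p = 0.013), as 1 of 10 lists called at 14 d. Of 9 adipose tissue genes Cidea and Pck1 rose (6 adjusted over the list alone), and the median log2 difference was 1.59 (camera adjusted p = 5.1e-14, adjusted p = 0.22 with an estimated correlation). Heart and skeletal muscle markers moved alongside, with a list mean of 7.06 log2 against 6.51 to 6.74 in naive mice, 0 of 17 past the threshold and a median of 0.42 (camera adjusted p = 0.00058, adjusted p = 0.55 with an estimated correlation). B cell genes had 0 of 21 members past the threshold over all genes, with 12 lower and 1 higher adjusted over the list alone and a median of -0.69 (camera adjusted p = 3.7e-16, adjusted p = 0.33 with an estimated correlation). The count of 22 genes was 12 without naive mouse 2 and 72 with array weights. The calls of Il12a and Rgs2 reached adjusted p = 0.072 without naive mouse 4, and that of Tnfsf10 0.080 without naive mouse 2.

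The 28 d pool had 3 genes higher and 3 lower. Arntl was 4.49-fold higher (standard error 0.24 log2, adjusted p = 0.0017), Lonrf3 2.20-fold (0.16, adjusted p = 0.0099) and Gemin8, of the complex that assembles spliceosomal particles, 1.68-fold (0.09, adjusted p = 0.0017). Nr1d1, Rgs2, a regulator of G protein signalling, and Zfp346 had log2 differences of -1.89, -1.21 and -0.71 (standard errors 0.26, 0.15 and 0.10). The call of Lonrf3 reached adjusted p = 0.052 without naive mouse 2 or 4. None of the 12, 18, 12 and 6 lists called for the pools at 4 h, 2 d, 7 d and 28 d holds with an estimated correlation.

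Pulmonary mice were then set against the subcutaneous pool of the same time, which is the direct comparison of routes. At 4 h, 1222 genes were higher and 1895 lower in pulmonary mice, among them chemokines and cytokines of inflammation. Cxcl2 was 145-fold higher (11.22 ± 0.83, SD, n = 3, against 4.04 log2 in the pool; standard error 0.78, adjusted p = 2e-05), Il6 about 107-fold, from 3.67 log2 in the pool, and Cxcl1 99.5-fold. Adipoq, a fat cell hormone, had a log2 difference of -2.84 (standard error 0.75), Fcna, a lectin of complement activation, -2.82 (0.86) and Gm19325 -2.70 (0.12). The call of Fcna reached adjusted p = 0.054 with array weights. The share of genes that were higher was 39.2% as deposited, 44.5% after a further quantile normalization and 49.5% with arrays centred on their medians. Of 26 inflammatory cytokines and chemokines 23 were higher (25 adjusted over the list alone; camera adjusted p = 2.3e-26, adjusted p = 0.24 with an estimated correlation). Of 13 glucocorticoid response genes 11 were higher (11 adjusted over the list alone; camera adjusted p = 1e-14), and this call, as 1 of 13, holds with an estimated correlation (adjusted p = 0.011). Of 19 neutrophil genes Il1r2, Clec4e, Trem1 and Hdc were higher, at 3.0, 2.89, 2.15 and 0.91 (4 adjusted over the list alone; camera adjusted p = 0.0086, adjusted p = 0.50 with an estimated correlation). S100a8 and S100a9, singled out after their values were seen, differed by -0.05 and 0.20 between the routes (adjusted p = 0.97 and 0.83). Of 9 adipose tissue genes Adipoq, Retn, Thrsp and Pck1 were lower (6 adjusted over the list alone), with a median of -1.28 (camera adjusted p = 0.020, adjusted p = 0.57 with an estimated correlation).

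At 2 d, 64 genes were higher and 64 lower in pulmonary mice than in the pool. Cxcl3 was 19-fold higher (8.23 ± 1.11, SD, n = 3, against 3.99 log2; standard error 0.78, adjusted p = 0.020), Lcn2, which withholds iron from bacteria, 5.44-fold and the mitotic kinase gene Cdk1 5.03-fold. Cd5l, Serpinb2, a serine protease inhibitor, and Prg4 had log2 differences of -4.80, -4.61 and -4.01 (standard errors 0.50, 0.27 and 0.63). Of 26 cell cycle genes 6 were higher, with Cdk1, Rrm2 and Birc5 at 2.33, 2.16 and 2.16, and 25 were higher adjusted over the list alone (camera adjusted p = 1.8e-30, adjusted p = 0.21 with an estimated correlation). Of 21 B cell genes Bank1, Blk and Fcrla were lower (12 adjusted over the list alone; camera adjusted p = 7.2e-10, adjusted p = 0.30 with an estimated correlation). Of 4 red blood cell genes Alas2, Slc4a1 and Bpgm were lower as well, at -1.62, -1.48 and -1.07 (3 adjusted over the list alone; camera adjusted p = 7.4e-07, adjusted p = 0.12 with an estimated correlation). Adipose tissue genes had 0 of 9 members past the threshold over all genes, 1 lower adjusted over the list alone and a median of -1.01 (camera adjusted p = 2e-04, adjusted p = 0.40 with an estimated correlation), and heart and skeletal muscle markers a median of -0.58 (camera adjusted p = 0.0086, adjusted p = 0.50 with an estimated correlation). None of the 21 lists called holds with an estimated correlation. The count of 128 genes was 242 without pulmonary mouse 10 and 85 without pulmonary mouse 12. Without pulmonary mouse 11 the log2 differences of Cxcl3 and Cd5l were 4.85 and -5.45. The call of Cdk1 reached adjusted p = 0.11 without pulmonary mouse 12 and that of Lcn2 0.061 with a trend and robust prior.

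At 7 d, limma called 0 genes between the routes, with 1929 at an unadjusted p under 0.05, 431 called without pulmonary mouse 13, 281 with array weights and 1 after a further quantile normalization or median centring. Of 13 MHC class II genes 0 passed over all genes and 13 were higher in pulmonary mice adjusted over the list alone, with Ctss, H2-Ea, H2-Eb1 and H2-DMb1 at log2 differences of 1.09, 1.07, 1.02 and 1.02 (camera adjusted p = 2.3e-17, adjusted p = 0.16 with an estimated correlation). Of 17 monocyte and interstitial macrophage genes 0 passed over all genes and 15 were higher adjusted over the list alone, with Ms4a7 at 2.77 (camera adjusted p = 4.2e-17, adjusted p = 0.26 with an estimated correlation). Muscle markers differed as well, with a median of -0.78 and 8 of 17 lower adjusted over the list alone (camera adjusted p = 1.6e-06, adjusted p = 0.26 with an estimated correlation), and adipose markers, with a median of -0.83 and 1 of 9 lower (camera adjusted p = 0.0012, adjusted p = 0.46 with an estimated correlation).

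At 14 d, 2 genes were higher and 11 lower in pulmonary mice. Mgl2 was 3.14-fold higher (7.55 ± 0.33, SD, n = 3, against 5.90 log2; standard error 0.28, adjusted p = 0.041). Gm19325, Zbtb16 and Cidea had log2 differences of -3.09, -2.17 and -1.91 (standard errors 0.12, 0.34 and 0.25). Of 13 glucocorticoid response genes Zbtb16 was lower, and 9 were lower adjusted over the list alone (camera adjusted p = 4.5e-16). This call, as 1 of 23, holds with an estimated correlation (adjusted p = 0.011). Of 9 adipose tissue genes Cidea and Pck1 were lower (7 adjusted over the list alone), with a median of -1.70 (camera adjusted p = 4.9e-16, adjusted p = 0.10 with an estimated correlation). Heart and skeletal muscle markers had a median of -0.41 (camera adjusted p = 1e-05, adjusted p = 0.30 with an estimated correlation). The count of 13 genes was 5 without pulmonary mouse 19. The call of Zbtb16 was lost without pulmonary mouse 17, 18 or 19 (adjusted p = 0.065, 0.06 and 0.095). That of Mgl2 was lost without pulmonary mouse 17 or 19 (adjusted p = 0.11 and 0.14). At 28 d limma called 0 genes, with 741 at an unadjusted p under 0.05 and 0 in each alternative. Of 18 immunoglobulin genes 0 passed over all genes and 4 were higher in pulmonary mice adjusted over the list alone, with Ighg1 at 2.06 and Igkc at 1.42 (camera adjusted p = 2.7e-14, adjusted p = 0.11 with an estimated correlation). None of the 24 lists called at 7 d or the 14 called at 28 d holds with an estimated correlation.

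**Figure D3:**
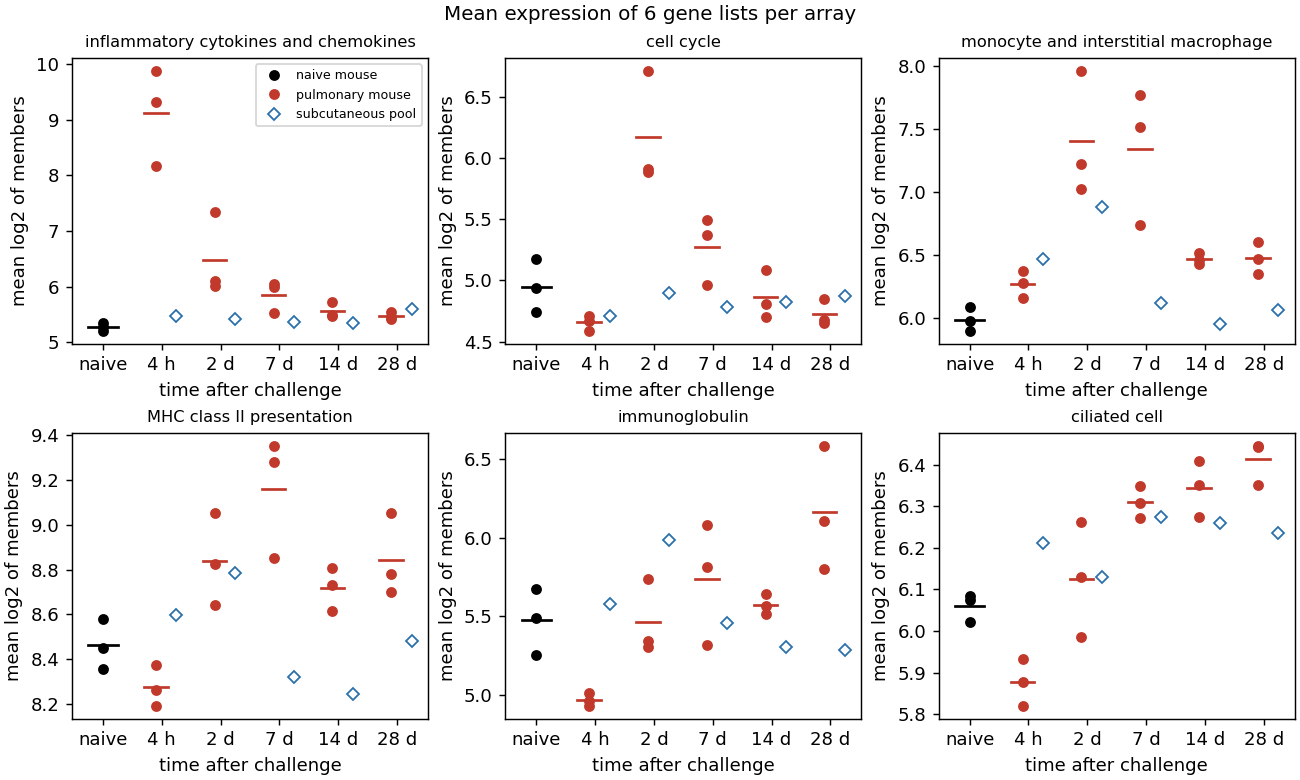
Mean log2 expression of the members of 6 gene lists (vertical axes) in naive mice and by time after challenge, with 1 filled point per mouse, lines at group means of 3 mice, and 1 open diamond per subcutaneous pool. The inflammatory list is high in the 3 pulmonary mice at 4 h, the cell cycle list in those at 2 d and the MHC class II list in those at 7 d.

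Over all 5 times together, with time in the model, limma called 0 genes between the routes, with 2555 at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were AU040972, Kcna3, Klrd1, Itga9 and Steap4 on the higher side in pulmonary mice, with log2 differences of 0.79, 0.43, 0.55, 0.26 and 1.57, and Ces1f, Muc16, Ubl4a, Dnajb2 and Cldn15 on the lower side, with -0.58, -0.59, -0.25, -0.26 and -0.30 (15 mice against 5 pools, adjusted p from 0.064 to 0.075). As the mean of the 5 single contrasts all 10 passed (adjusted p from 0.00095 to 0.011), without the 4 h arrays AU040972, Kcna3 and Ces1f, and without the 28 d arrays Itga9, Steap4, Ces1f, Muc16 and Cldn15. With 1 mouse left out, 7 of the 10 passed without mouse 13 of the 7 d group (all but Itga9, Dnajb2 and Cldn15), Ces1f, Muc16 and Ubl4a without mouse 17, Ces1f and Muc16 without mouse 8, and Ces1f without mouse 22. Inflammatory cytokines and chemokines had 0 of 26 members past the threshold over all genes and 8 higher adjusted over the list alone, with a median of 1.04 (camera adjusted p = 2e-13, adjusted p = 0.19 with an estimated correlation). Adipose tissue genes had 8 of 9 members lower adjusted over the list alone, with a median of -0.83 (camera adjusted p = 2.2e-07, adjusted p = 0.19 with an estimated correlation), and heart and skeletal muscle markers 9 of 17, with a median of -0.46 (camera adjusted p = 3.8e-06, adjusted p = 0.19 with an estimated correlation). None of the 24 lists called holds with an estimated correlation. The test of whether the route difference changed with time called 1105 genes, and 1861 with array weights. Such changes count as spread in the model of time and route, so its 0 genes do not show that the routes are alike. The mean of the 5 single contrasts takes its spread from mice within groups alone. The count for the route was 4 without pulmonary mouse 8 of the 4 h group, 14 without mouse 13 of the 7 d group, 6 without mouse 17 of the 14 d group, 1 without mouse 22 of the 28 d group, 16 without the 4 h arrays, 27 without the 28 d arrays, 0 as a test on 5 pairs and 762 as the mean of the 5 single contrasts.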

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

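The tests of alternative activation of macrophages and of a route difference in adipose genes, and the counts of other splits, were chosen only after the results were seen. The tests of cavity macrophages and of further adipose genes were also set up for patterns already seen in the pools. The first 4 results stand out because the difference between the routes was itself tested. The pulmonary mice and the pool of the same time differed in 3117 genes at 4 h, 128 at 2 d and 13 at 14 d, and the route difference changed with time in 1105 genes. Each rests on 1 pool per time, which is assumed to vary like a single mouse and has no replicate check. Named genes that differed between the routes at 4 h were Cxcl2, Il6 and Cxcl1, with log2 differences of 7.18, 6.74 and 6.64, and Adipoq, Fcna and Gm19325, with -2.84, -2.82 and -2.70. At 2 d they were Cxcl3, Lcn2 and Cdk1, with 4.24, 2.44 and 2.33, and Cd5l, Serpinb2 and Prg4, with -4.80, -4.61 and -4.01. At 14 d they were Mgl2, with 1.65, and Gm19325, Zbtb16 and Cidea, with -3.09, -2.17 and -1.91. For Gm19325 the spread comes from mice at low levels, not from pools at a high one.

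Cd5l, Prg4 and Serpinb2 were high in the subcutaneous 2 d pool, with Cd5l at 10.17 log2 against 4.08 to 4.37 in the other subcutaneous pools, and they also rose less in the pulmonary 2 d mice, at 1.24, 1.89 and 0.83 above naive (adjusted p = 0.041, 0.017 and 0.016; Cd5l at 6.69 in mouse 11, which has the highest adipose list mean of the pulmonary mice, 6.46, and at 4.56 and 4.88 in the other mice). Macrophages of the pleural or peritoneal cavity may have been carried into this pool: the median of 7 of their marker genes, 0.46 above naive with 6 of 7 higher, lay at percentile 100 of 10000 random lists matched for expression. Random lists do not vary together as markers of 1 cell type do, and only the pool with the pattern was tested, so the percentile is weak support. The 7 differences were uneven, with Timd4 at 2.05, Selp at 1.78, F10 at 0.70 and Garnl3, the median itself, at 0.46, of which Timd4 alone passed, while the most abundant markers gave Icam2 at 10.88 log2 in the pool against 10.89 in naive mice and Gata6 at 7.78 against 7.66, and 3 of the 7 genes (Icam2, Gata6 and Tgfb2) already lie above the array median in naive lungs. Selp and F10 were also high in pulmonary 4 h mice, at 7.73 and 4.69 log2 against 5.72 and 4.75 in the pool. Naive means were 3.94 and 4.04, and Cd5l was at 3.96 to 4.05 in those 4 h mice. Timd4 and Garnl3 were at 4.09 and 4.80 there, against 5.81 and 5.13 in the pool. Alternative activation of lung macrophages stays open. The median of Retnla, Chil3, Mrc1, Mgl2 and Ccl24, of which only Mgl2 is in no other list, was 0.865. With 2 times the median standard error of a single gene added it was 1.44, past the 1 it would need. That margin is not the standard error of the median itself. Ccl24 alone passed, at 2.11, with Retnla at 1.19, Chil3 at 0.865, Mgl2 at 0.278 and Mrc1 at 0.201. In pulmonary 7 d mice Retnla, Chil3, Mrc1 and Mgl2 were at 9.545, 11.4, 9.345 and 7.202 log2. Naive means were 8.502, 9.645, 8.633 and 5.924. Cd5l lay at 3.974 to 4.168 in those 7 d mice, and Ccl24 at 3.797 against 4.018 in naive mice. No sort is named that would remove either cell type, and a route effect in this 1 pool is untested.

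Adipose tissue genes were higher in the subcutaneous pools than in most pulmonary mice. Adipose tissue taken along with the lungs is a candidate source: 7 further adipose genes had a median 0.218 above naive in the 14 d pool, with 7 of 7 higher, at percentile 99.93 of the random lists. Only this pool was tested, and it has the highest mean of the first adipose list of all arrays, 7.06 log2. Random lists also do not vary together as markers of 1 tissue do, so the percentile is not independent support. None of the 7 passed singly, and the most abundant of them, Slc36a2 and Cox8b, stood at 8.47 and 7.74 log2 against 8.21 and 6.65 in naive mice, with 3 of the 7 (Slc36a2, Cox8b and Dgat2) above the array median in naive lungs. The mean of the first adipose list was above the highest pulmonary mouse, 6.46, in 3 of 5 pools, while the 7 d pool, at 6.16, lay within the pulmonary range and the 28 d pool, at 5.58, below all 3 pulmonary mice of its time (5.59 to 6.19), so a route difference cannot be told apart from tissue carried along in single pools.

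The 6 arrays of each pulmonary group and the naive mice allow 10 splits of 3 against 3, too few for a share under 0.05. The real counts were 5163, 1447, 877, 34 and 75 genes at the 5 times, and the highest other split gave 0 at each, so 1 of 10 splits was as large. For any difference over the naive and pulmonary groups, chance is unlikely: 1 of 100 splits of the 18 arrays, the real one with 6823 genes, was as large. The other splits were random draws, of which the highest gave 4249 genes, and 1 of 100 is the smallest share they allow. For the route over all times the splits decide nothing: the real count was 0, so that 100 of 100 choices had to be as large, and the highest other was 1.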

How the results depend on the processing

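The comparison with pulmonary 28 d mice in place of naive mice was chosen after the data were seen. The cause of the changes below was not tested, except that a minimum fold, fewer arrays, fewer groups or another estimate of the spread by construction alter what can pass. Of 18 counts, 18 stayed within 1.5 times with a trend and robust prior and 18 without dim probe sets, but the prior ended 6 of 86 named calls: Snord14e (adjusted p = 0.065), Ccl8 and Ighg1 at 28 d (0.068 and 0.075), Fcna (0.050), Lcn2 (0.061) and Cdk1 (0.062). Signal over background, for which no call was used, limits folds from levels under the lower quartile of 3.86 to 3.93 log2. A further quantile normalization gave 3 genes for the subcutaneous 4 h pool and 1 for pulmonary against subcutaneous at 7 d, and median centring 1 for the latter. A minimum of 1.5-fold gave 1639, 497, 340 and 46 genes for pulmonary against naive at 4 h, 2 d, 7 d and 28 d, 1484 for the routes at 4 h and 2157 for the F test over groups. Array weights gave 1969 and 188 for pulmonary at 7 d and 28 d, 10, 223, 2 and 72 for the pools at 4 h, 2 d, 7 d and 14 d, 281 for the routes at 7 d and 1861 for route by time. A fit of 2 groups alone gave 635, 561 and 134 for pulmonary at 2 d, 7 d and 28 d. It ended the 28 d calls of Ighg1 (adjusted p = 0.16) and Ptgs2 (0.098). The route over all times gave 16 genes without 4 h, 27 without 28 d and 762 as the mean of 5 contrasts. Against pulmonary 28 d mice, 7 d gave 238 genes and 14 d 0, Dbp and Cyp1a1 at 7 d turned to 0.0832 and 0.611 (adjusted p = 0.97 and 0.34), and these 2 and 13 other calls of 32 named genes were lost.

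With each mouse left out in turn, counts for pulmonary against naive ranged from 4253 to 5285 at 4 h, 519 to 1751 at 2 d, 225 to 1418 at 7 d, 9 to 25 at 14 d and 11 to 48 at 28 d. For the pools they ranged from 1 to 2 at 4 h, 62 to 107 at 2 d and 12 to 19 at 14 d. Between the routes they ranged from 85 to 242 at 2 d, 0 to 431 at 7 d, 5 to 10 at 14 d and 0 to 14 over all times. Named genes lost their call in 71 of 498 such fits and gained one in 13. Camera called 266 of 624 list tests; 260 of these calls were lost with an estimated correlation, and 72 were also made by fry (13 of 15 for pulmonary at 4 h, 4 of 14 at 14 d, 2 of 18 for the 2 d pool and 0 of 12 for the 7 d pool). The mean of several probe sets of a gene was not run, since each gene has 1.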

Other observations

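The tests of the clock genes were chosen only after the result was seen, as were the genes named in the next sentences. Transcripts of the signature cytokines of T helper cells were low, with naive means of 3.73 log2 for Il17a and 3.65 for Ifng. Both lie under the lower quartile of the arrays, where a change can be missed. In pulmonary mice the log2 differences from naive of Il17a were 0.04, -0.08, 0.23, -0.07 and 0.01 from 4 h to 28 d (adjusted p from 0.20 to 1.0), and those of Ifng, the cytokine of Th1 cells, 0.04, 0.12, 0.04, -0.01 and 0.02 (adjusted p from 0.32 to 1.0). Il5 and Il13, cytokines of type 2 immunity, differed by at most 0.10 and 0.13. Alveolar macrophage genes rose in 7 of 17 members at 2 d (8 higher and 1 lower adjusted over the list alone) and in 8 of 17 at 7 d, where Car4 and Krt19 fell (10 and 2 adjusted over the list alone). Chil3, a chitinase-like lectin, was at 0.99 and 1.75, and Ctsk, a cysteine protease, at 1.39 and 1.55. The camera adjusted p was 3.9e-05 and 3.0e-05, and adjusted p = 0.23 at both times with an estimated correlation.

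Goblet cell and mucus genes also rose in part. At 2 d 4 of 15 members passed (6 adjusted over the list alone): Slc26a4 at 3.12, Bpifb1, a secreted airway defence protein, at 1.97, the mucin Muc5b, 2.38-fold higher, and Muc4 at 0.40 (camera adjusted p = 4.9e-07, adjusted p = 0.26 with an estimated correlation). Mouse 11 stood apart, with a mean of this list of 6.62 log2 against 5.24 and 5.37 in the other 2 d mice and 4.59 to 4.76 in naive mice, and a mean of the type 2 response list of 5.97 against 4.88 and 4.97. Its means of the adipose list, 6.46 against 5.62 and 5.36, and of the eosinophil and mast cell list, 4.71 against 4.29 and 4.33, were the highest of the 2 d mice as well. Elastin, Eln, was the fibroblast and matrix gene with the largest difference at 7 d, at 1.42, and 3 of 18 members of that list rose, the others being Tnc at 1.06 and Fn1 at 0.39 (6 adjusted over the list alone; camera adjusted p = 0.00020, adjusted p = 0.26 with an estimated correlation).

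Circadian clock genes differed from naive lungs in pulmonary mice from 2 d to 28 d, with Arntl higher by 1.52 to 1.89 and Dbp lower, at -2.59 to -2.82. A response to the challenge that wanes with the inflammatory genes is argued against as the whole cause. The clock score, the mean of 3 activator genes minus that of 7 output genes, was 2.20 above naive at 2 d and 1.94 at 28 d (standard error 0.26), a ratio of 0.884, while the inflammatory list went from 1.20 to 0.20. The hour of the day at which lungs were taken stays open: the activator and output arms had opposite signs in 4 of 4 groups, but any shift of the clock would give this, and the hour is not given in the sources used here and cannot be told apart from the groups. The subcutaneous pools lay 0.14, 2.45, 2.09, 1.42 and 2.13 above naive from 4 h to 28 d, with shifts of the inflammatory list of 0.07 to 0.33, and the pulmonary 4 h mice 0.99, and an effect of vaccination itself stays open and untested.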
